A study of Mus musculus with 18 samples.

How the data were processed

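Polyadenylated RNA from mouse colonic epithelial cells was sequenced by the submitters as 18 libraries, 3 for each of 6 groups: wild type, FIP1 knockout and FIP2 knockout, each from distal and proximal colon. Per the labels the epithelium was released with 30 mM EDTA and reads were 150 nt long. The submitters' processing notes name STAR 2.5, TopHat, HTSeq 0.6.1 and DESeq2, with the genome builds GRCm38 and mm10. The deposited values used here are counts per gene, and the deposited FPKM values served as an alternative. Each file held 54532 genes, of which 21436 had no count in any library. For 30034 of 30034 genes checked, the ratio of count to FPKM gave 1 length across libraries (tolerance 1e-04). The FPKM values were therefore scaled to the library total without a further normalization factor. Of the 54409 gene identifiers found in the M21 annotation of GRCm38, 53499 (98.3%) had the same position there. The library strand was not stated, so counts of overlapping or antisense genes are uncertain.

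Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalization, the filterByExpr filter (17692 genes kept) and 1 quasi-likelihood fit to all 18 libraries, with a square root of the common dispersion of 0.234. The 11 contrasts were each knockout against wild type and the knockouts against each other within a segment, proximal against distal within a genotype, and for each knockout the difference of its effect between segments. P-values were adjusted with the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05. With 3 libraries a group, the test borrows the spread from other genes. CPM values are counts scaled to the library total adjusted by the TMM factor. A fold against a group with no count was computed against a floor of 3 counts over the group, and ratios against 1 to 3 counts carry a 95% counting interval.

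Of 39 gene lists written from general knowledge, 38 had the 5 measured members needed for a set test; neutrophils, with 3, had none. Camera (limma 3.58.1) compared each list with all other genes at a preset correlation between genes of 0.01. It was repeated with a correlation estimated for each list, and fry was run as a test of whether a list's genes move on balance one way, without reference to other genes. List medians were also computed with members lacking counts placed at their bound, which moved 13 of 351 medians.

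The genes named are Rab11fip1 and Rab11fip2; the 10 largest rises and 10 largest falls of each contrast (5 each way for the differences between segments) among called protein-coding genes with a mean of at least 1 CPM, a non-predicted symbol and non-overlapping libraries; up to 4 members of each described list in order of adjusted p; and Muc2, Reg3b, Reg3g, Lcn2, Slc26a3, Aqp8, Il18, Il1b, Rab11a, Rab25 and Myo5b. Some genes under this rule are not reported. Groups, contrasts, lists, this rule and most alternatives were set before the data were examined. The FPKM mean minimum of 0.5, the brain gene list, the genes in the closing observations, the medians at bounds and 3 alternatives were chosen after the values were seen.

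The alternatives were relative log expression in place of TMM; no filter on low counts; at least 10 CPM in 3 libraries; a fit to the compared libraries alone; a replicate block; DESeq2 1.42.0; limma on log2(FPKM + 1) and log2(FPKM + 0.1), and on the former without a filter; and leaving out each library in turn. The 3 added later removed wild-type proximal library 2, FIP2 knockout distal library 1 or the mitochondrially encoded genes. The pairing of libraries across segments by their number was checked from correlations of residuals, which were 0.355, 0.200 and 0.242 for FIP2 knockout. Only there were all 3 over 0.1, so the numbers were taken to pair distal and proximal libraries of the FIP2 knockout. In FIP1 knockout they were 0.200, 0.175 and 0.0683, each above the highest correlation between different numbers (-0.00297), so pairing there stays open. In wild type they were -0.0816, 0.110 and 0.169. All contrasts come from the fit without the block. For comparisons between segments the block alternative paired libraries by number in all 3 genotypes. No 2 libraries of the same group were duplicates, and pairs from different groups were not checked.

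The precision was tested on simulated data made from these counts, with 100 genes changed 2-fold and 100 changed 4-fold. For FIP1 knockout against wild type in the distal colon edgeR recovered 44% and 94%, and for the difference between segments 21% and 70% for FIP1 and 14% and 70% for FIP2. The pattern shared by the knockouts was set against data in which all libraries were simulated from the wild-type means and both comparisons shared the simulated wild-type libraries. Reads were not analysed here, so exon-level counts of the targeted genes were not examined. Python 3.11.15 with matplotlib 3.10.9 drew the figures.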

Results

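Polyadenylated RNA was measured in epithelial cells released from the mouse colon with 30 mM EDTA. The libraries came from wild-type C57BL/6J mice, from mice lacking Rab11-FIP1 (FIP1 knockout) and from mice lacking Rab11-FIP2 (FIP2 knockout). Rab11-FIP1 and Rab11-FIP2 are adaptor proteins that bind the small GTPase Rab11 on recycling endosomes, the compartment that returns proteins to the epithelial surface. Distal and proximal colon were sequenced separately, with 3 libraries in each of the 6 groups. The summed counts ran from 11193308 to 22062300 per library, and 17692 genes were tested. Expression is given as CPM, counts scaled to the library total, with means and standard deviations (SD) over n = 3 libraries. Changes are on the log2 scale with their standard error (SE), and adjusted p-values come from edgeR's quasi-likelihood test with the Benjamini-Hochberg method. The labels do not say whether the 3 libraries of a group came from separate mice, so the p-values may measure technical spread. Counting intervals and floors cover counting error only.

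Rab11fip1 (ENSMUSG00000031488, chromosome 8, 27138773 to 27174646, minus strand, build GRCm38) was still counted in every FIP1 knockout library. Its level was 48.5 ± 2.10 CPM (SD, n = 3) in distal FIP1 knockout libraries, with a range of 46.4 to 50.6, and 116 ± 20.5 CPM in distal wild-type libraries, with a range of 92.0 to 128. In the proximal colon it was 67.5 ± 14.7 CPM in the knockout and 138 ± 41.6 CPM in wild type. The fall was -1.25 ± 0.22 (SE) distally, with an adjusted p of 0.00070 by edgeR, and -1.03 ± 0.22 proximally, with an adjusted p of 0.0037. FIP2 knockout libraries kept 133 ± 17.6 CPM distally and 132 ± 27.7 CPM proximally. Rab11fip2 (ENSMUSG00000040022, chromosome 19, 59902884 to 59943654, minus strand) was lower by -1.07 ± 0.27 in distal FIP2 knockout libraries, at 3.52 ± 0.914 CPM against 7.38 ± 0.0842 CPM, with an adjusted p of 0.011. That call was lost without FIP2 knockout distal library 1, where the change was -0.88 and the adjusted p 0.057. Proximally it was lower by -0.84 ± 0.28, at 3.67 ± 0.529 CPM against 6.61 ± 1.91 CPM, with an adjusted p of 0.047. The proximal call was lost without wild-type proximal library 2 (-0.61, adjusted p 0.14) or 3 (-0.88, adjusted p 0.088), and without FIP2 knockout proximal library 1 (-0.96, adjusted p 0.063), 2 (-0.80, adjusted p 0.13) or 3 (-0.77, adjusted p 0.13). FIP1 knockout libraries held 6.02 ± 0.585 CPM of Rab11fip2 distally and 4.72 ± 1.53 CPM proximally. Their proximal range of 3.34 to 6.37 CPM overlapped that of the FIP2 knockout, 3.31 to 4.28 CPM. The counts are summed over the whole gene (up to 7 annotated exons for Rab11fip1, up to 6 for Rab11fip2), and the labels do not give the deleted part. The presence of counts from the rest of the locus therefore checks nothing about the alleles.

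**Figure D1:**
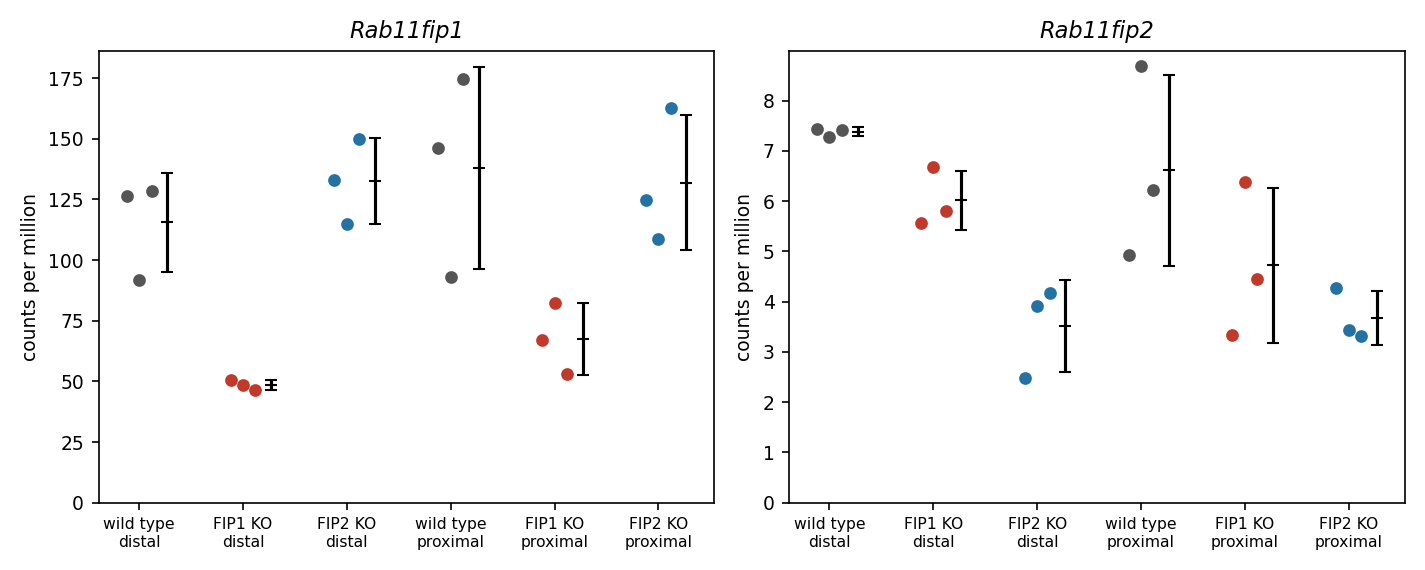
CPM of Rab11fip1 and Rab11fip2 (linear axes) in each of the 18 libraries by group, with bars for the mean and SD of 3 libraries. Rab11fip1 sat between 46.4 and 50.6 CPM in the 3 distal FIP1 knockout libraries and between 92.0 and 128 CPM in the 3 distal wild-type libraries.

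The first component of the expression matrix held 27.1% of the variance and separated proximal from distal libraries. The second held 24.2% and separated the 6 wild-type libraries from all 12 knockout libraries, and the third, with 10%, separated the knockouts from each other. The fourth, with 6.72%, set apart wild-type proximal library 2, which also carried transcripts of forebrain neurons. The mitochondrially encoded genes took a larger share of the counts in wild type, at 24.4 ± 7.24% (SD, n = 3) distally and 23.9 ± 3.35% proximally, than in FIP1 knockout (15.2 ± 2.79% and 15.7 ± 4.10%) or FIP2 knockout (13.9 ± 3.12% and 17.3 ± 2.42%). The cytochrome oxidase gene mt-Co1 was the most counted gene, with 5.99 to 17.7% of a library.

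**Figure D2:**
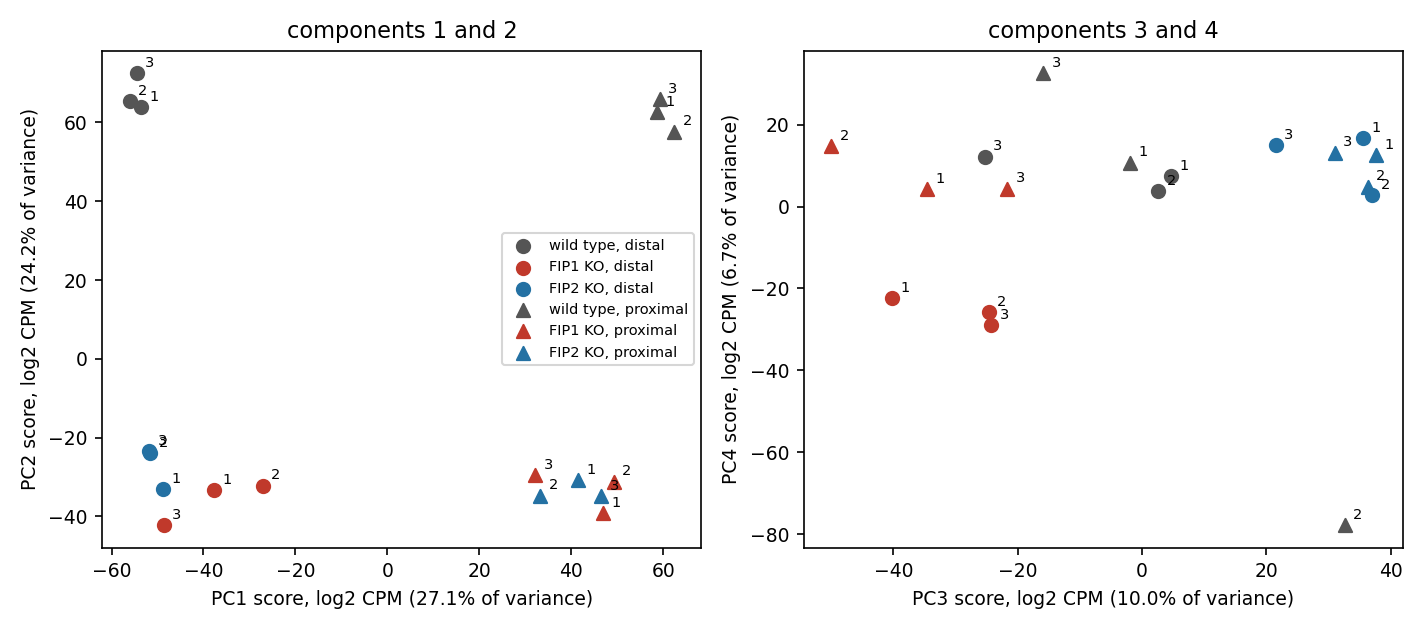
Position of each of the 18 libraries on the principal components of log2 CPM, coloured by genotype with distal and proximal colon marked apart. The second component, with 24.2% of the variance, parts the 6 wild-type libraries from the 12 knockout libraries, and the fourth, with 6.72%, sets wild-type proximal library 2 apart.

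The distal FIP1 knockout colon was compared with distal wild type to ask what the loss of Rab11-FIP1 does to this epithelium, which the series title links to spontaneous inflammation. Interferon-stimulated genes were higher throughout: 47 of the 50 measured members rose and 0 fell (48 rose when adjusted over the list alone). The group passed the competitive test camera (adjusted p 6.09e-36, and adjusted p = 0.0379 with an estimated correlation). The RNA-binding antiviral gene Ifit2 rose by 6.10 ± 0.42 (SE), from 1.41 ± 0.229 CPM to 97.8 ± 23.6 CPM. The immunity-related GTPase Iigp1 rose by 6.08 ± 0.51, the nucleic acid sensor Zbp1 by 3.51 ± 0.33 and the GTPase Irgm2 by 2.97 ± 0.28. Antigen presentation genes rose with them. Of 23 class I genes 17 rose and 0 fell (20 adjusted over the list alone; adjusted p = 0.0764 with an estimated correlation), among them Nlrc5, the transactivator of class I genes, by 5.97 ± 0.37, and the peptide transporter Tap1 by 2.93 ± 0.32. Of 11 class II genes 9 rose (adjusted p = 0.107 with an estimated correlation). The invariant chain Cd74 went from 23 ± 16.2 CPM to 781 ± 171 CPM, a rise of 5.09 ± 0.41, and H2-Aa rose by 5.87 ± 0.49.

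Transcripts of immune cells were also higher in this comparison. The list for T cells and innate lymphocytes had 16 of 33 members risen and 0 fallen (24 adjusted over the list alone; adjusted p = 0.0379 with an estimated correlation), with granzyme Gzma up by 6.11 ± 0.53, Gzmb by 3.62 ± 0.58 and the T cell coreceptor Cd8a by 1.96 ± 0.31. Of 24 B and plasma cell genes 18 rose (23 adjusted over the list alone; adjusted p = 0.269 with an estimated correlation), including the immunoglobulin A heavy chain Igha by 4.98 ± 0.70 and the joining chain Jchain by 5.14 ± 0.89. Macrophage and dendritic cell genes had 5 of 21 members risen (adjusted p = 0.385 with an estimated correlation), with Ms4a6c up by 3.64 ± 0.78. Fibroblast genes had 7 of 23 risen (adjusted p = 0.385 with an estimated correlation), with the matrix protein Fbln1 up by 3.14 ± 0.48. Of 3 measured neutrophil genes 2 rose, too few for the set test. Among 30 cytokines and chemokines 12 rose and 2 fell (adjusted p = 0.269 with an estimated correlation). The lymphocyte attractant Cxcl9 rose by 4.53 ± 0.64 and Tnf by 2.33 ± 0.33, while Cx3cl1, which attracts mononuclear phagocytes, fell by 1.07 ± 0.19. The monocyte attractant Ccl8, with no count in wild type, was at least 46.7-fold higher. Il1b was higher by 2.22 ± 0.62 (adjusted p 0.019), a call lost without wild-type distal library 1 (1.95, adjusted p 0.074), wild-type distal library 2 (2.06, adjusted p 0.070) or FIP1 knockout distal library 3 (1.84, adjusted p 0.097). Il18 (0.33 ± 0.31, adjusted p 0.53) and Lcn2 (2.72 ± 1.18, adjusted p 0.13) did not pass.

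Epithelial defence genes took part. Of 31 antimicrobial and epithelial defence genes 12 rose and 2 fell (adjusted p = 0.279 with an estimated correlation). The secreted lectin Reg3g rose by 9.72 ± 0.79, to 363 ± 320 CPM from 0.430 ± 0.516 CPM, and Reg3b rose by 9.51 ± 0.96. The nitric oxide synthase Nos2 rose by 4.57 ± 0.45. In contrast, the Paneth and goblet cell ribonuclease Ang4 fell by 6.50 ± 1.07, to 4.69 ± 3.10 CPM from 421 ± 107 CPM. Reg3g and Reg3b, Ang4, and several histocompatibility genes have close paralogs, so reads shared within those families leave single members uncertain. Wound-associated genes had 11 of 23 members risen and 0 fallen (adjusted p = 0.27 with an estimated correlation), with the surface antigen Ly6a up by 3.29 ± 0.40 and the growth factor Hbegf by 1.48 ± 0.23. The zymogen granule protein Sycn fell by 4.03 ± 0.46, to 36.0 ± 6.87 CPM from 589 ± 106 CPM.

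Sterol metabolism rose in the same libraries. Of 26 cholesterol synthesis genes 18 rose and 0 fell (19 adjusted over the list alone; adjusted p = 0.0379 with an estimated correlation). Sqle, which makes the epoxide that is closed into the first sterol, rose by 1.63 ± 0.23, from 47.2 ± 14.3 CPM to 146 ± 10.4 CPM, and the sterol demethylase Cyp51 rose by 1.30 ± 0.18. The list of fatty acid oxidation genes and targets of PPAR nuclear receptors is called the fatty acid oxidation list below. A change of this mixed list does not by itself measure oxidation. It had 11 of 32 members fallen and 2 risen (adjusted p = 0.279 with an estimated correlation), and the lipid droplet protein Plin2 fell by 1.43 ± 0.23. Of 18 clock genes 9 fell and 1 rose (adjusted p = 0.342 with an estimated correlation), with the clock output gene Dbp down by 2.21 ± 0.34. Tuft cell genes had 11 of 26 fallen and 0 risen (adjusted p = 0.269 with an estimated correlation), with changes of -2.17 ± 0.33 for the kinase Matk and -1.81 ± 0.36 for the channel Trpm5. Proliferation genes had 9 of 35 risen (20 adjusted over the list alone; adjusted p = 0.503 with an estimated correlation), with the replication helicase subunit Mcm3 up by 1.31 ± 0.23.

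The lists for goblet cells (adjusted p 0.211), brush border (0.478), absorptive colonocytes (0.734), tight and adherens junctions (0.315) and the Rab11 trafficking machinery (0.431) did not pass camera. The mucin Muc2 stood at 3687 ± 1609 CPM against 3563 ± 429 CPM (0.05 ± 0.32), and the chloride exchanger Slc26a3, the water channel Aqp8, Rab25 and the motor Myo5b were not called. Rab11a itself rose by 0.83 ± 0.18, to 167 ± 30.7 CPM from 94.1 ± 9.05 CPM. Across all genes 1564 were higher and 1322 lower in the distal FIP1 knockout by edgeR, and 1788 and 703 by limma on log2(FPKM + 1). The 6 libraries did not overlap between the groups for 35.8% of all tested genes, where chance gives 10%. Without FIP1 knockout distal library 3 the total was 1775 in place of 2886. With the preset correlation camera called 19 of 38 lists (13 up, 6 down), and 3 held with an estimated one: interferon-stimulated genes, T cells and innate lymphocytes, and cholesterol synthesis.

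In the proximal colon the FIP1 knockout differed from wild type in many of the same groups. Interferon-stimulated genes had 43 of 50 members risen and 1 fallen (adjusted p = 0.0294 with an estimated correlation), led by Iigp1, up by 7.87 ± 0.59 (SE) to 89.6 ± 43.8 CPM from 0.397 ± 0.293 CPM, and by Ifit2, up by 4.93 ± 0.39. Class II presentation had 7 of 11 risen (adjusted p = 0.096 with an estimated correlation), with Cd74 up by 7.05 ± 0.46 to 813 ± 148 CPM and H2-Aa by 7.31 ± 0.53. Class I presentation had 15 of 23 risen (adjusted p = 0.0559 with an estimated correlation), with Nlrc5 up by 5.28 ± 0.35 and the immunoproteasome subunit Psmb8 by 2.76 ± 0.27. T cell and innate lymphocyte genes had 11 of 33 risen (19 adjusted over the list alone; adjusted p = 0.0294 with an estimated correlation), with Gzma up by 3.41 ± 0.33 and Itgae, an integrin of intraepithelial lymphocytes, by 1.90 ± 0.29. B and plasma cell genes had 4 of 24 risen (adjusted p = 0.607 with an estimated correlation), Igha among them by 3.67 ± 0.67. The list's median of 1.99 was 1.29 once the members without a count in a group were put at their lower bounds.

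Cholesterol synthesis rose here as well, with 19 of 26 genes up and 1 down (adjusted p = 0.0294 with an estimated correlation); Sqle rose by 1.82 ± 0.23 to 131 ± 9.15 CPM and Hmgcs1 by 1.73 ± 0.22. The fatty acid oxidation list fell, with 15 of 32 members down and 0 up (adjusted p = 0.0294 with an estimated correlation). The fatty acid hydroxylase Cyp4b1 fell by 4.97 ± 0.56, to 4.95 ± 2.86 CPM from 151 ± 58.3 CPM, and the changes were -4.16 ± 0.53 for Angptl4, -2.67 ± 0.34 for Pdk4 and -1.90 ± 0.26 for the nuclear receptor Ppara. Xenobiotic and oxidative defence genes had 23 of 40 members fallen and 0 risen (28 fallen when adjusted over the list alone; adjusted p = 0.0559 with an estimated correlation), with changes of -3.28 ± 0.43 for the carboxylesterase Ces1g and -2.32 ± 0.35 for Ces2a. The disaccharidase Sis, a brush border enzyme typical of the small intestine, fell by 5.86 ± 0.34, to 2.48 ± 0.341 CPM from 143 ± 16.9 CPM.

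Enteroendocrine genes fell in the proximal FIP1 knockout colon, with 10 of 26 down and 0 up (17 adjusted over the list alone; adjusted p = 0.0191 with an estimated correlation). The granule proteins Chga and Chgb fell by 1.62 ± 0.26 and 1.34 ± 0.24, the serotonin synthesis enzyme Tph1 by 1.45 ± 0.25 and the prohormone carboxypeptidase Cpe by 1.76 ± 0.30. Neurons express some of these genes and wild-type proximal library 2 carried forebrain transcripts. Without it the changes were -1.85, -1.22, -1.37 and -1.16 in the same order, all still called, and the list passed camera (adjusted p 8.69e-07). Forebrain transcripts were also still called lower by edgeR without that library. Gria1 was at -6.41 (adjusted p 9.06e-05), Ddn at -5.76 (0.00106) and Grin2b at -4.27 (0.000438). Leaving the library out therefore cannot exclude a neuronal share in the enteroendocrine falls. Tuft cell genes had 11 of 26 fallen (adjusted p = 0.0874 with an estimated correlation), with Dclk1 down by 1.59 ± 0.25. Proliferation genes had 15 of 35 risen (27 adjusted over the list alone; adjusted p = 0.341 with an estimated correlation), with Uhrf1, which maintains DNA methylation in dividing cells, up by 1.69 ± 0.21. Antimicrobial genes had 10 of 31 risen and 1 fallen (adjusted p = 0.341 with an estimated correlation), a call lost without FIP1 knockout proximal library 2 (adjusted p 0.11). Nos2 rose by 5.51 ± 0.49, Reg3g by 4.88 ± 0.58, the dual oxidase Duox2 by 1.82 ± 0.26 and its maturation factor Duoxa2 by 1.89 ± 0.25. Wound-associated genes had 9 of 23 risen and 4 fallen (adjusted p = 0.341 with an estimated correlation), Ly6a by 3.87 ± 0.42. Tnf rose by 4.43 ± 0.39, to 10.2 ± 3.30 CPM.

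The synaptic vesicle gene Slc17a7 had no count in the proximal FIP1 knockout, and in wild type it had 11.5 CPM in proximal library 2, which carried brain transcripts, against 1.29 and 1.57 CPM in the other two. It was still called lower by edgeR without that library (adjusted p 0.0021). The enteric neuron and glia list had 5 of 14 fallen (adjusted p = 0.189 with an estimated correlation), with a change of -2.22 ± 0.40 for the synaptic protein Snap25, or -1.54 (adjusted p 0.0054) without that library. The summed level of 19 enteric genes was 31.3, 32.9 and 30.3 CPM in the wild-type libraries and 37.7, 22.2 and 30.5 CPM in the knockout ones. Lcn2 was lower by 4.04 ± 1.17 (adjusted p 0.026), a call lost without that library (-1.0, adjusted p 0.58) and without FIP1 knockout proximal library 1 (-4.02, adjusted p 0.090), 2 (-4.06, adjusted p 0.069) or 3 (-4.04, adjusted p 0.085). Muc2 (-0.31 ± 0.32), Slc26a3, Aqp8, Il1b, Rab25 and Myo5b were not called. Rab11a (0.41 ± 0.18, adjusted p 0.14) passed without wild-type proximal library 2 (0.66, adjusted p 0.012), and Il18 (0.78 ± 0.31, adjusted p 0.11) passed without that library (1.24, adjusted p 0.012) or FIP1 knockout proximal library 1 (1.05, adjusted p 0.041). In all, 1185 genes were higher and 1219 lower by edgeR, and 1279 higher and 533 lower by limma on log2(FPKM + 1). Of all tested genes 26.6% had no overlap between the groups (10% by chance). The total of 2404 fell to 1483 without FIP1 knockout proximal library 1 and to 1287 in a fit to the 6 libraries alone. Camera called 20 lists and 5 held with an estimated correlation: interferon-stimulated genes, cholesterol synthesis, T cells and innate lymphocytes, fatty acid oxidation and enteroendocrine cells.

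The same comparison was made for the FIP2 knockout in the distal colon. Class I presentation rose, with 21 of 23 genes up (22 adjusted over the list alone; adjusted p = 0.0675 with an estimated correlation); Nlrc5 rose by 6.45 ± 0.37 (SE) and B2m, the invariant light chain of class I, by 2.54 ± 0.24. Interferon-stimulated genes had 42 of 50 risen (adjusted p = 0.0675 with an estimated correlation), with Iigp1 up by 6.67 ± 0.51 to 95.7 ± 16.6 CPM from 0.928 ± 0.343 CPM. Class II presentation had 7 of 11 risen (adjusted p = 0.204 with an estimated correlation), with H2-Aa up by 6.76 ± 0.51 to 1162 ± 306 CPM. T cell and innate lymphocyte genes had 17 of 33 risen (adjusted p = 0.0675 with an estimated correlation), with Cd8a up by 2.64 ± 0.30 and Gzmb by 4.65 ± 0.56. B and plasma cell genes did not pass camera here (median 0.12, adjusted p 0.418), with Igha at 24.6 ± 7.58 CPM against 8.38 ± 7.77 CPM in wild type. Antimicrobial genes had 11 of 31 risen and 3 fallen (adjusted p = 0.357 with an estimated correlation), with Reg3g up by 6.45 ± 0.75, Nos2 by 4.15 ± 0.44 and Duoxa2 by 2.47 ± 0.25. Wound-associated genes had 9 of 23 risen (adjusted p = 0.367 with an estimated correlation), with Hbegf up by 2.26 ± 0.23. Cytokines had 11 of 30 risen and 3 fallen (adjusted p = 0.367 with an estimated correlation), with Tnf up by 2.82 ± 0.33 and Il15, a survival factor for intraepithelial lymphocytes, down by 2.12 ± 0.26.

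The endoplasmic reticulum stress list had 10 of 26 members risen and 3 fallen in the distal FIP2 knockout (adjusted p = 0.367 with an estimated correlation). The chaperone Hspa5 rose by 1.32 ± 0.24, to 1868 ± 182 CPM from 747 ± 144 CPM, Hsp90b1 by 1.10 ± 0.23 and Manf by 1.00 ± 0.21. The stress-induced transcription factor Ddit3 fell by 1.14 ± 0.22. Of 18 clock genes 10 fell and 2 rose (adjusted p = 0.367 with an estimated correlation), Dbp by 3.16 ± 0.36 down and Nfil3, which acts against Dbp at its target sites, by 1.71 ± 0.32 up. Plin2 fell by 1.37 ± 0.23 in a fatty acid oxidation list with 9 of 32 fallen and 2 risen (adjusted p = 0.329 with an estimated correlation). Cholesterol synthesis had 8 of 26 risen (adjusted p = 0.268 with an estimated correlation), with Cyp51 up by 1.21 ± 0.18. Tuft cell genes had 9 of 26 fallen (adjusted p = 0.357 with an estimated correlation), with Dclk1 down by 1.21 ± 0.25. Mitochondrially encoded transcripts had 4 of 13 fallen (adjusted p = 0.367 with an estimated correlation). The largest of those falls was in the complex I subunit mt-Nd3, by 4.23 ± 0.31, to 7.58 ± 2.46 CPM from 143 ± 64.8 CPM. The transfer RNA genes on either side of it, mt-Tg and mt-Tr, averaged 0.0391 and 0.189 CPM over the FIP2 knockout libraries, against 13.5 and 5.04 CPM in wild type. The complex I subunit mt-Nd1 was at 11337 ± 3583 CPM against 18030 ± 6953 CPM distally. A local difference in sequence or alignment was not tested, so mt-Nd3 does not stand for the list.

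The manganese exporter Slc30a10 fell by 7.82 ± 0.71, to 0.376 ± 0.263 CPM from 89.2 ± 23.7 CPM. Pbld1, of the phenazine biosynthesis-like protein family, fell by 4.42 ± 0.44. The calcium-activated chloride channel regulator Clca4b, which has close paralogs, rose by 9.24 ± 0.51 to 3258 ± 246 CPM from 5.39 ± 2.76 CPM. The erythroid membrane protein Ermap, with 3 counts in wild type, was 264 times higher (95% counting interval 90.1 to 1283). Ccl8 was at least 49.7-fold higher. Rab11a rose by 0.96 ± 0.18, and Muc2 (-0.48 ± 0.32), Slc26a3, Aqp8, Il18, Il1b, Lcn2, Rab25 and Myo5b were not called. EdgeR called 1615 genes higher and 1659 lower, and limma on log2(FPKM + 1) 1503 higher and 942 lower. Of all tested genes 37.6% had no overlap (10% by chance). The total of 3274 was 1853 without wild-type distal library 3 and 2050 without FIP2 knockout distal library 1. Camera called 17 lists and 0 held with an estimated correlation (3274 single genes passed edgeR and 5767 had an unadjusted p under 0.05), while fry, which tests whether a list's genes move on balance one way, called 19.

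In the proximal FIP2 knockout colon T cell and innate lymphocyte genes rose in 22 of 33 members and fell in 0 (29 risen when adjusted over the list alone; adjusted p = 0.0146 with an estimated correlation). Gzma rose by 4.63 ± 0.34 (SE), to 37.4 ± 8.07 CPM from 1.52 ± 0.209 CPM, Cd8a by 2.69 ± 0.27 and Itgae by 2.48 ± 0.29. B and plasma cell genes had 17 of 24 risen (22 adjusted over the list alone; adjusted p = 0.211 with an estimated correlation), with Igha up by 4.93 ± 0.71 to 272 ± 56.8 CPM. That list's median was 3.58, or 3.03 with members at their lower bounds. Class II presentation had 7 of 11 risen (adjusted p = 0.12 with an estimated correlation), with H2-Aa up by 8.22 ± 0.55 and Cd74 by 7.26 ± 0.46. Interferon-stimulated genes had 32 of 50 risen (adjusted p = 0.12 with an estimated correlation), with Iigp1 up by 7.86 ± 0.59 and Ifit2 by 4.18 ± 0.38. Class I presentation had 17 of 23 risen (adjusted p = 0.12 with an estimated correlation), with Nlrc5 up by 4.91 ± 0.35. For macrophages and dendritic cells the median (-0.02) and the mean (0.48) differed in sign and camera called the list up (adjusted p 0.0317; adjusted p = 0.573 with an estimated correlation). That call was lost without wild-type proximal library 1 (adjusted p 0.15), wild-type proximal library 3 (0.26) or FIP2 knockout proximal library 3 (0.061).

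The fatty acid oxidation list fell in the proximal FIP2 knockout, with 18 of 32 members down and 0 up (adjusted p = 0.0245 with an estimated correlation). Cyp4b1 fell by 3.07 ± 0.51 and Pdk4 by 1.83 ± 0.33. Xenobiotic defence had 20 of 40 fallen (adjusted p = 0.183 with an estimated correlation), with the organic anion pump Abcc2 down by 2.76 ± 0.44. Brush border genes had 10 of 31 fallen (adjusted p = 0.573 with an estimated correlation), with Anks4b, a scaffold of the intermicrovillar adhesion complex, down by 1.07 ± 0.19. Endoplasmic reticulum stress genes had 14 of 26 risen and 2 fallen (adjusted p = 0.12 with an estimated correlation), with Hspa5 up by 1.31 ± 0.24, Manf by 1.22 ± 0.22 and Creld2 by 1.22 ± 0.23. Of 18 clock genes 13 fell and 1 rose (adjusted p = 0.275 with an estimated correlation), Dbp by 2.42 ± 0.35. Tuft cell genes had 11 of 26 fallen and 1 risen (adjusted p = 0.232 with an estimated correlation). Proliferation genes had 11 of 35 risen (adjusted p = 0.394 with an estimated correlation) and stem cell and Wnt target genes 5 of 24 (adjusted p = 0.375 with an estimated correlation), with the hyaluronan receptor Cd44 up by 1.41 ± 0.31. Antimicrobial genes had 12 of 31 risen and 2 fallen (adjusted p = 0.275 with an estimated correlation), with the epithelial oxidase Nox1 up by 4.08 ± 0.49 and Duoxa2 by 2.59 ± 0.26.

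The alpha-galactosyl transferase Ggta1 rose by 7.45 ± 0.59, to 202 ± 54.7 CPM from 1.30 ± 1.64 CPM, and the lipoxygenase Alox15, with no count in wild type, was at least 20.3-fold higher. The cobalamin receptor Cubn fell by 4.42 ± 0.39, to 1.99 ± 0.998 CPM from 42.7 ± 17.0 CPM. Ptgs2, which makes prostaglandins, fell by 5.15 ± 1.11, and its level in the wild-type libraries ran from 0.52 to 11 CPM. The thyroid protein Tg (26.1 ± 24.1 CPM), the gastric lipase Lipf and the airway protein Bpifa1 were counted in FIP2 knockout proximal libraries and had no count in wild type; DESeq2 did not call Lipf or Bpifa1, and Bpifa1 was lost without wild-type proximal library 1 (9.85, adjusted p 0.055) or 3 (9.85, adjusted p 0.056). Muc2 (-0.36 ± 0.32), Slc26a3, Aqp8, Il18, Il1b, Rab25 and Myo5b (-0.42 ± 0.16, adjusted p 0.086) did not pass. Rab11a passed without wild-type proximal library 2 (0.61, adjusted p 0.014), and Lcn2 (-3.21 ± 1.11, adjusted p 0.058) without library 1 (-3.68, adjusted p 0.049) or 3 (-3.80, adjusted p 0.0087), while without library 2 it was -0.17 (adjusted p 0.93). EdgeR called 1344 genes higher and 1250 lower, and limma on log2(FPKM + 1) 1490 higher and 581 lower. Of all tested genes 29.3% had no overlap (10% by chance). The total of 2594 became 1555 without wild-type proximal library 3, 1690 and 1658 without FIP2 knockout proximal libraries 1 and 2, and 1511 in a fit to the 6 libraries alone. Of the 18 lists called, fatty acid oxidation and T cells with innate lymphocytes held with an estimated correlation.

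**Figure D3:**
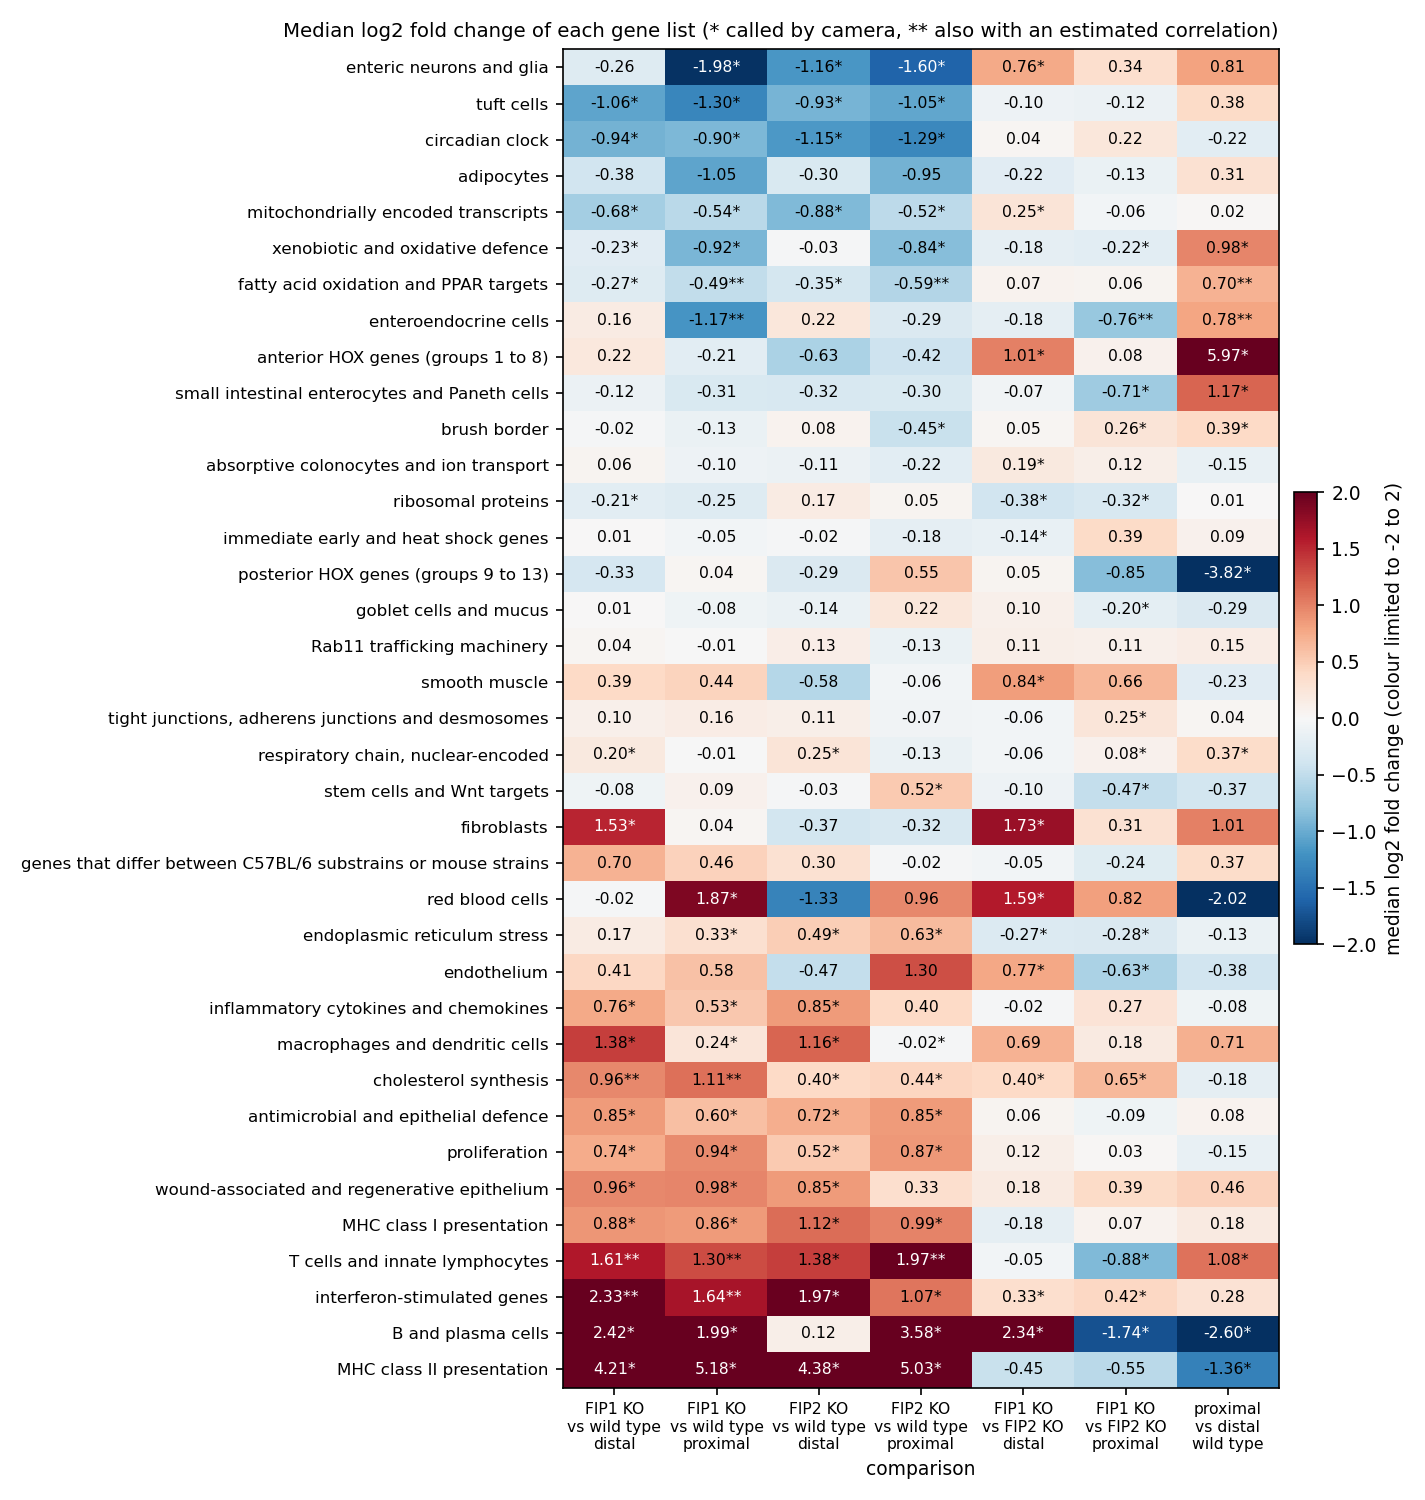
Median log2 change of each gene list in 7 comparisons, with colour limited to -2 to 2, 1 star for lists called by camera and 2 stars for those that also held with an estimated correlation; sex-linked genes and neutrophils are left out. Interferon-stimulated genes had medians of 2.33, 1.64, 1.97 and 1.07 in the comparisons with wild type.

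**Figure D4:**
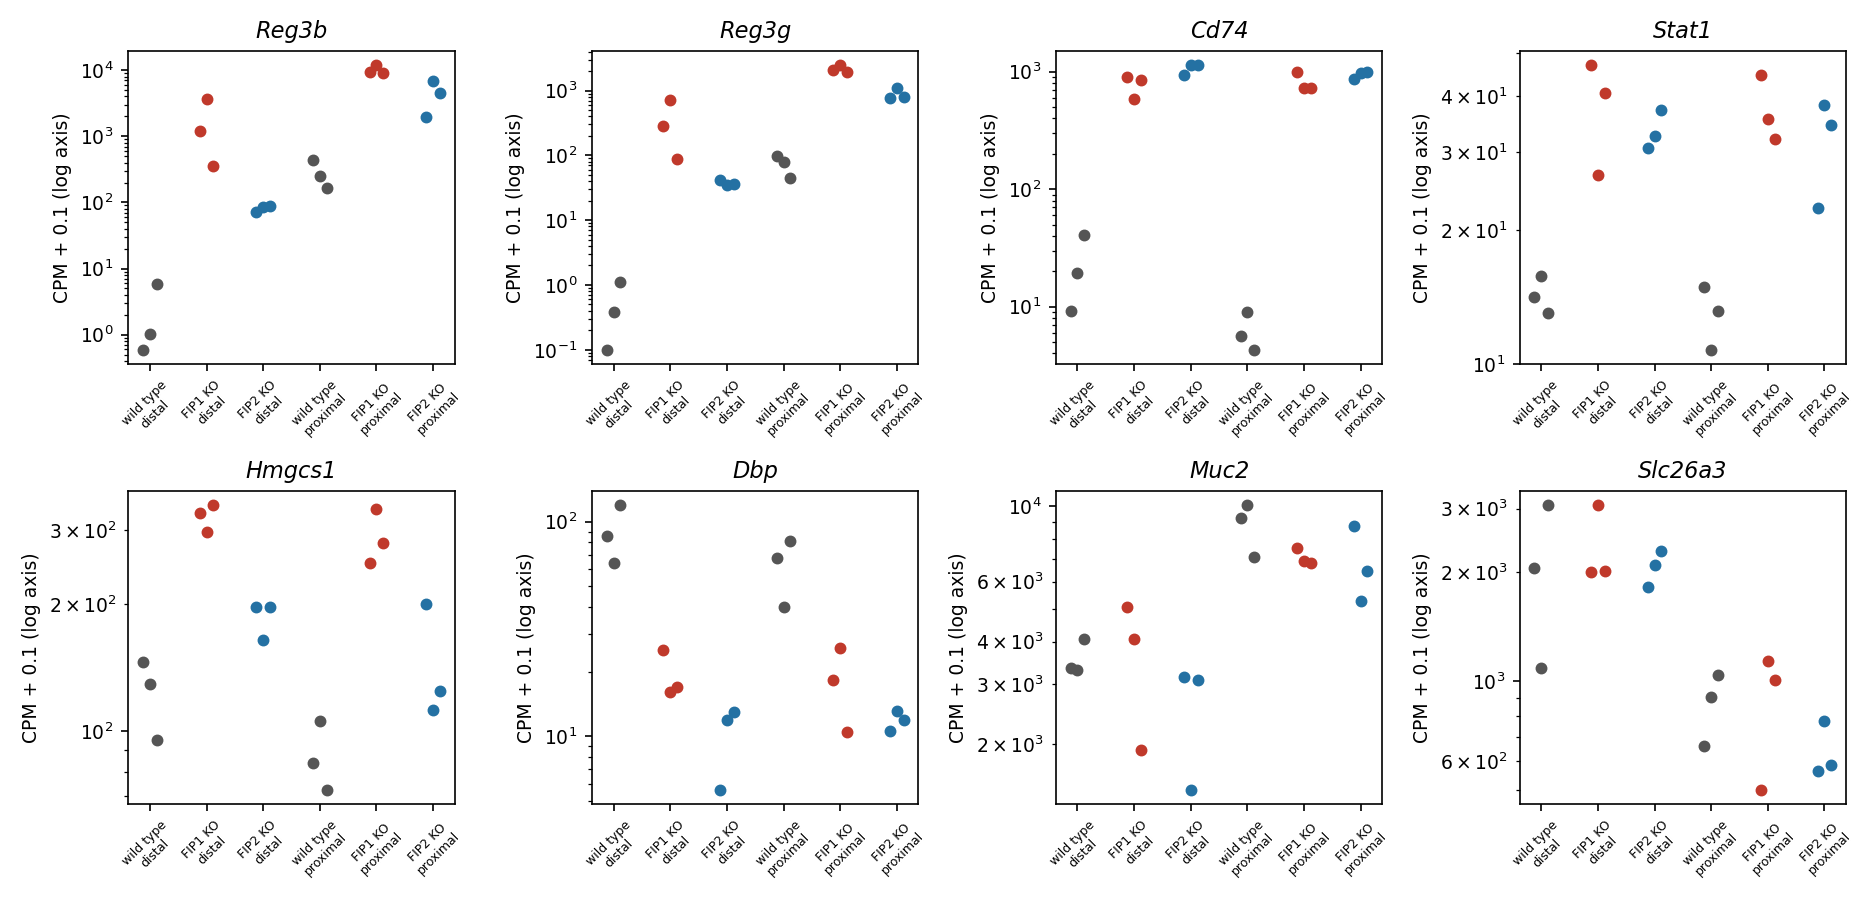
CPM + 0.1 (log axes) of 8 genes in each of the 18 libraries, by group; points are libraries. Cd74 averaged 781 CPM in distal FIP1 knockout and 1065 CPM in distal FIP2 knockout libraries, against 23 CPM in distal wild type.

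The knockouts shared much of their difference from wild type. In the distal colon 888 genes were higher and 845 lower in both knockouts and 6 went opposite ways, where independent calls would give 143 and 124 genes in common. The comparisons use the same wild-type libraries, so their calls are not independent and those figures are no test of the overlap. In the proximal colon 687 were higher and 609 lower in both and 8 opposite. The distal total of 1733 shared genes was 1068 without wild-type distal library 3 and 1147 without FIP1 knockout distal library 3. Across genes, which are not independent replicates, the log2 changes correlated at 0.716 distally and 0.736 proximally. All libraries, wild type included, were also simulated from the wild-type means with no genotype effect. With the simulated wild-type libraries shared by both comparisons the correlations were 0.514 and 0.542. In all 4 comparisons with wild type 373 genes were higher and 256 lower. The lists called by camera in all 4 in the same direction were 8 up (interferon-stimulated genes, both antigen presentation lists, T cells and innate lymphocytes, macrophages and dendritic cells, antimicrobial defence, cholesterol synthesis and proliferation) and 4 down (tuft cells, fatty acid oxidation, the clock and mitochondrially encoded transcripts). With an estimated correlation 0 of these 12 held in all 4, since 0 lists held in the distal FIP2 knockout, where camera with the preset correlation called 17 and fry 19. The macrophage and dendritic cell call was also lost in 3 of the comparisons when 1 library was left out: in proximal FIP1 knockout without wild-type proximal library 1 (adjusted p 0.234) or 3 (0.403) or FIP1 knockout proximal library 2 (0.250), in distal FIP2 knockout without wild-type distal library 1 (0.246) or 2 (0.0689) or FIP2 knockout distal library 1 (0.0513) or 2 (0.0628), and in the proximal FIP2 knockout as given above. Single libraries also ended the calls of mitochondrially encoded transcripts in distal FIP1 (0.0944 without wild-type distal library 2) and proximal FIP2 knockout (0.102 without wild-type proximal library 2), and of the clock (0.0550 without wild-type proximal library 3) and antimicrobial genes (0.110 without FIP1 knockout proximal library 2) in proximal FIP1 knockout.

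**Figure D5:**
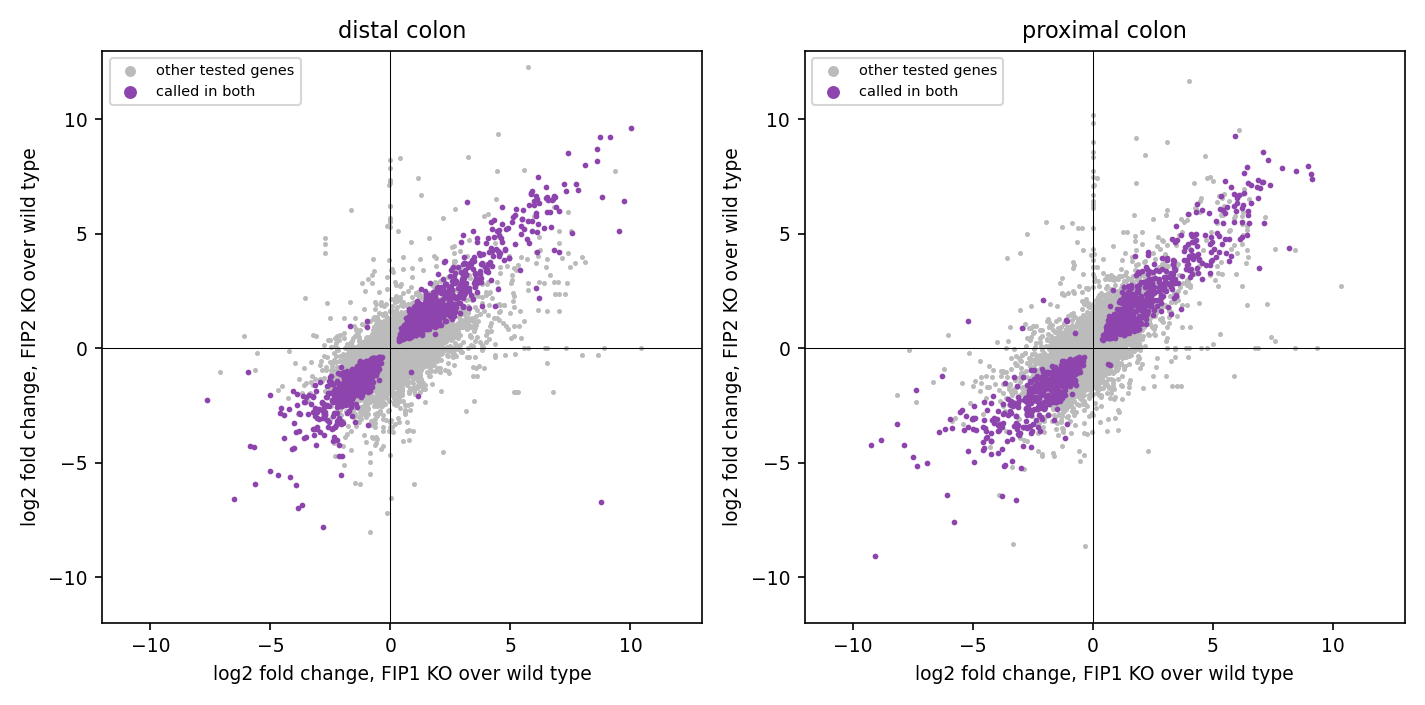
Log2 change of each tested gene in the FIP1 knockout (horizontal axis) against the FIP2 knockout (vertical axis), each relative to wild type, in distal and proximal colon, with genes called in both comparisons in purple. Correlations across genes were 0.716 and 0.736, and 6 and 8 genes were called in opposite directions.

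The knockouts were also compared with each other. In the distal colon 5 of 24 B and plasma cell genes were called higher in the FIP1 than in the FIP2 knockout, and 23 when adjusted over the list alone (median 2.34; adjusted p = 0.264 with an estimated correlation), with Igha higher by 3.43 ± 0.64 (SE). Reg3g was higher by 3.26 ± 0.54 and Reg3b by 4.40 ± 0.75. The epithelial sodium channel subunits Scnn1b and Scnn1g were higher by 1.21 ± 0.20 and 2.06 ± 0.35. The atrial myosin light chain Myl7 was higher by 4.03 ± 0.35, at 31.8 ± 5.34 CPM against 1.95 ± 0.727 CPM, and mt-Nd3 by 3.57 ± 0.30. The zinc finger gene Zfp990, which has close paralogs and no count in distal FIP2 knockout libraries, was at least 215-fold higher. Hoxb6 was higher by 3.25 ± 0.43 in an anterior HOX list with 3 of 15 risen (adjusted p = 0.264 with an estimated correlation). Genes lower in the FIP1 knockout included the chaperone Hsph1 (-2.68 ± 0.39), the kinase subunit Camk2b (-2.67 ± 0.25), the bile acid binding protein Fabp6 (-3.78 ± 0.40) and the nucleoside phosphorylase Pnp2 (-4.90 ± 0.38), which has a close paralog. EdgeR called 215 genes higher and 114 lower, limma on log2(FPKM + 1) 252 and 78, and 22.7% of all tested genes had no overlap (10% by chance). The total of 329 was 107 and 180 without FIP1 knockout distal libraries 1 and 3, 164 and 117 without FIP2 knockout distal libraries 1 and 2, and 644 by DESeq2. Of 14 lists called by camera 0 held with an estimated correlation; 2560 genes had an unadjusted p under 0.05, and fry called 4 lists.

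In the proximal colon 10 of 26 cholesterol synthesis genes were called higher and 0 lower in the FIP1 than in the FIP2 knockout (16 adjusted over the list alone; adjusted p = 0.0954 with an estimated correlation); Mvd, an enzyme of the mevalonate part of the pathway, was higher by 0.99 ± 0.17. Enteroendocrine genes were lower, with 5 of 26 fallen (10 adjusted over the list alone; adjusted p = 0.0323 with an estimated correlation), with a change of -1.49 ± 0.26 for the prohormone convertase Pcsk1. Of 33 T cell and innate lymphocyte genes 2 were called lower (9 adjusted over the list alone; adjusted p = 0.212 with an estimated correlation), with Cd8a at -1.4 ± 0.25. The claudin Cldn4 was higher by 2.47 ± 0.31, at 131 ± 42.8 CPM against 23.5 ± 11.8 CPM, and the giant transporter Abca13 by 3.38 ± 0.35. Sis was lower by 2.36 ± 0.31, the kallikrein Klk1 by 1.47 ± 0.27 and Ggta1 by 7.28 ± 0.57. Gsta1, a glutathione transferase, was higher by 2.38 ± 0.32. EdgeR called 235 genes higher and 251 lower, limma on log2(FPKM + 1) 155 and 157, and 27.1% of all tested genes had no overlap (10% by chance). The total of 486 was 251 and 193 without FIP1 knockout proximal libraries 1 and 2, 277, 245 and 225 without FIP2 knockout proximal libraries 1, 2 and 3, and 1034 by DESeq2. Camera called 15 lists, or 8 without FIP1 knockout proximal library 1, and the enteroendocrine list held with an estimated correlation.

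Proximal and distal colon were compared within each genotype. In wild type the patterning genes parted the segments. Hoxb6 was higher proximally by 6.64 ± 0.34 (SE), at 140 ± 55.8 CPM against 1.41 ± 0.301 CPM, and the transcription factor Osr2 by 9.70 ± 0.48. The distal marker Hoxb13 was lower by 5.86 ± 0.69 and Hoxd13, with no proximal count, was at least 282-fold lower. Of 15 anterior HOX genes 9 rose and 5 fell (adjusted p = 0.115 with an estimated correlation), and of 10 posterior ones 7 fell (adjusted p = 0.129 with an estimated correlation). The anterior median of 5.97 was 4.96 with members at their bounds, and the posterior median of -3.82 was -2.85. The fatty acid oxidation list rose proximally in 23 of 32 members and fell in 1 (adjusted p = 0.0196 with an estimated correlation), with Cyp4b1 up by 7.51 ± 0.68 and Pparg, a nuclear receptor for fatty acids, by 2.40 ± 0.21. Xenobiotic defence had 23 of 40 risen and 2 fallen (adjusted p = 0.0643 with an estimated correlation), with the glucuronosyl transferase Ugt1a1 up by 4.88 ± 0.38. Enteroendocrine genes had 10 of 26 risen and 1 fallen (adjusted p = 0.0397 with an estimated correlation), with secretin (Sct) up by 4.23 ± 0.35 and neurotensin (Nts) by 8.92 ± 0.77. Sis was higher by 7.82 ± 0.39 and the bile acid transporter subunit Slc51a by 7.97 ± 0.56. Reg3b and Reg3g were higher by 6.90 ± 0.87 and 7.40 ± 0.76.

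Lower proximally in wild type were the proton pump Atp12a (-10.36 ± 0.97, at 0.493 ± 0.272 CPM against 621 ± 266 CPM), Il18 (-2.01 ± 0.32), Aqp8 (-1.70 ± 0.38) and the protease Casp14 (at least 150-fold, with no proximal count). Muc2 was higher by 1.30 ± 0.33. Slc26a3 was lower by 1.25 ± 0.33, a call lost without wild-type distal library 3 (-0.86, adjusted p 0.093) or proximal library 1 (-1.09, adjusted p 0.064). Lcn2 was higher by 4.26 ± 1.20, a call lost without wild-type proximal library 2 (1.23, adjusted p 0.52), distal library 1 (4.29, adjusted p 0.061) or distal library 2 (3.77, adjusted p 0.081). EdgeR called 1585 genes higher and 1308 lower, while limma on log2(FPKM + 1) had the larger number lower, 951 higher and 1313 lower. Of all tested genes 28.3% had no overlap (10% by chance). The total of 2893 was 1810 in a fit to the 6 libraries alone. Camera called 11 lists, of which fatty acid oxidation and enteroendocrine cells held with an estimated correlation.

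The FIP1 knockout kept this pattern for Hoxb6, higher proximally by 5.22 ± 0.31 (SE), Osr2, by 8.63 ± 0.44, and Hoxb13 (-6.58 ± 0.72). Pparg was higher by 1.34 ± 0.20 in a fatty acid oxidation list with 13 of 32 risen (adjusted p = 0.0133 with an estimated correlation). B and plasma cell genes were lower proximally, with 16 of 24 fallen (adjusted p = 0.0827 with an estimated correlation); the B cell surface protein Ms4a1 fell by 4.01 ± 0.58 and the B cell factor Pax5, with no proximal count, was at least 153-fold lower. The transcription factor Tbx3 was higher by 6.92 ± 0.57, and the calcium channel Trpv6 was lower by 6.75 ± 0.83. Reg3g was higher by 2.57 ± 0.52, Il18 lower by 1.57 ± 0.31, and Muc2 (0.94 ± 0.33, adjusted p 0.10) did not pass. There were 521 genes higher and 646 lower by edgeR and 354 and 618 by limma on log2(FPKM + 1), with 23.2% of all tested genes without overlap (10% by chance). The total of 1167 was 695 without FIP1 knockout distal library 3. Of 11 lists called by camera fatty acid oxidation held with an estimated correlation.

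In the FIP2 knockout T cell and innate lymphocyte genes were higher proximally in 19 of 33 members (29 adjusted over the list alone; adjusted p = 0.0155 with an estimated correlation), with Gzma higher by 2.44 ± 0.28 (SE) and Cd8a by 1.82 ± 0.25. Anterior HOX genes had 9 of 15 risen and 1 fallen (adjusted p = 0.0155 with an estimated correlation), with Hoxb6 higher by 8.15 ± 0.39 and a list median of 6.11, or 3.88 with members at their bounds. The fatty acid oxidation list had 14 of 32 risen (adjusted p = 0.017 with an estimated correlation), with Pdk4 higher by 4.05 ± 0.40. Sis was higher by 6.47 ± 0.46, Reg3b by 5.76 ± 0.80 and the mucin glycosyl transferase Gcnt3 by 2.12 ± 0.27. Hoxd13 was at least 553-fold lower and Casp14 at least 440-fold lower, each with no proximal count, and Slc26a3 was lower by 1.69 ± 0.34. The pancreatic enzymes Pnlip, Ctrb1 and Cela2a were called lower proximally, and all 3 calls were lost without FIP2 knockout distal library 1 (-6.50, -5.06 and -4.23, adjusted p 0.22, 0.18 and 0.21). The calls of Pnlip and Ctrb1 were also lost without FIP2 knockout proximal library 1 (adjusted p 0.076 and 0.057), 2 (0.079 and 0.058) or 3 (0.094 and 0.074), and that of Cela2a without library 3 (0.056). EdgeR gave 882 genes higher and 794 lower and limma on log2(FPKM + 1) 621 and 662, with 26.6% of all tested genes without overlap (10% by chance). The total of 1676 was 1069 without FIP2 knockout proximal library 3. With the replicate number as a block the enteroendocrine (adjusted p 0.0685) and cytokine (adjusted p 0.0546) lists were no longer called. Camera called 14 lists, or 9 without FIP2 knockout proximal library 1, and the 3 described first held with an estimated correlation.

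The last comparisons asked whether a knockout's effect differed between segments. For FIP1 the change of enteroendocrine genes was lower in the proximal than in the distal colon, with 4 of 26 members called lower and 0 higher in the difference (12 adjusted over the list alone; adjusted p = 0.00339 with an estimated correlation). The difference was -2.50 ± 0.42 (SE) for Cpe, -2.72 ± 0.47 for the tachykinin precursor Tac1 and -1.96 ± 0.34 for Chgb. Without wild-type proximal library 2, which carried forebrain transcripts, they were -1.90, -2.86 and -1.84, all still called, and the list passed camera (adjusted p 2.12e-10). The other called member, Pcsk1, was then -1.43 and no longer called (adjusted p 0.0849 by edgeR). The forebrain transcript Gria1 was still called (-6.12, adjusted p 0.0114) and Ddn was not (-5.63, adjusted p 0.0524). Leaving that library out therefore cannot exclude a neuronal share. The cytosolic phospholipase Pla2g4c differed by 6.30 ± 0.85, the lipoprotein Apob by -2.15 ± 0.37 and the neutrophil attractant Cxcl5 by -6.29 ± 0.97. For FIP2 the largest differences included the nucleoside transporter Slc28a3 (3.93 ± 0.59), Slc30a10 (4.85 ± 0.86) and the ion transport regulator Fxyd4 (4.51 ± 0.70). Limma on log2(FPKM + 1) did not call Slc28a3 (1.23) or Slc30a10 (1.38). EdgeR, fitted without the replicate number, called 24 genes higher and 90 lower for FIP1 and 13 higher and 45 lower for FIP2. With the replicate number as a block it called 262 and 202 genes. The FIP1 total of 114 was 64, 42 and 71 without wild-type distal libraries 1, 2 and 3, 45, 59 and 72 without FIP1 knockout distal libraries 1, 2 and 3, and 56 and 40 without FIP1 knockout proximal libraries 1 and 3. The FIP2 total of 58 was 33 without wild-type distal library 2, 37 without FIP2 knockout distal library 3, and 35, 35 and 38 without FIP2 knockout proximal libraries 1, 2 and 3. Of 10 lists called for FIP1 (18 without FIP1 knockout proximal library 2) the enteroendocrine list held with an estimated correlation; of 19 for FIP2, 0 did, with 1778 genes at an unadjusted p under 0.05 and 2 lists called by fry.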

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

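The tests of shared controls, immune cells, collection and brain transcripts were chosen after the results they address were seen. For 114 genes the FIP1 knockout effect differed between proximal and distal colon by an interaction test, and for 58 genes the FIP2 effect did. Both counts come from the fit that ignores pairing by library number, and both were larger with the replicate number as a block. For FIP1 the largest log2 differences were Ang4 6.53, Pla2g4c 6.30, Itln1 5.19, Ifi27l2a 3.99 and Fxyd4 3.801 upward, and Cyp3a25 -10.29, Ddn -7.19, Gria1 -7.19, Ccl7 -6.42 and Cxcl5 -6.29 downward. Without FIP1 knockout distal library 1 Cyp3a25 was -6.2 with an adjusted p of 1. Ddn and Gria1 are forebrain transcripts, at 17.3 and 10.3 CPM in wild-type proximal library 2 and at most 2.85 and 2.70 CPM in the other two; without that library they were -5.63 (adjusted p 0.0524) and -6.12 (adjusted p 0.0114). For FIP2 they were Cyp2f2 6.24, Slc30a10 4.85, Fxyd4 4.51, Slc28a3 3.93 and Lsp1 3.77 upward, and Ccl7 -9.56, Cxcl5 -6.16, Lrg1 -5.96, Cxcl1 -5.90 and Thbs2 -5.60 downward. Leaving out each library in turn ended the calls of Ang4, Itln1, Ifi27l2a, Fxyd4, Cyp3a25, Ddn and Ccl7 for FIP1 and of Lsp1, Cxcl5, Lrg1 and Cxcl1 for FIP2 at least once.

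Relabelling the knockout and wild-type libraries within segments gave as many genes in 4 of 40 draws for FIP1 (real 114, highest other 844) and 4 of 40 for FIP2 (real 58, highest other 2985), the real grouping included. The other draws that reached the real count kept more knockout labels in 1 segment than in the other, which turns the shared knockout effect into a difference between segments, so these draws do not measure chance. The 12 FIP1 and 13 FIP2 draws that kept equal numbers gave at most 1 and 0 genes and are too few for a share under 0.05. For each of the other 9 comparisons 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts and the highest others were 2886 and 0 for FIP1 distal, 2404 and 6 for FIP1 proximal, 3274 and 0 for FIP2 distal, and 2594 and 0 for FIP2 proximal. They were 329 and 0 for the knockouts compared distally, 486 and 0 proximally, and 2893 and 0, 1167 and 1, and 1676 and 1 for proximal against distal in wild type, FIP1 and FIP2 knockout.

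The knockouts differed from wild type in much the same way. Sharing the wild-type libraries was argued against as the whole cause, since the covariance of the log2 changes exceeded its simulated mean by 0.698 in the segment where the excess was smaller (0.810 against 0.111, highest simulated 0.117). The simulation redrew the wild-type libraries at the fitted spread, so it does not cover a shift of all the real ones. More immune cells in the knockout preparations may account for the class II genes, and the values cannot decide this. The 95% intervals below come from redrawing the members of the lists. They treat genes as replicates and do not measure the spread between libraries. In no comparison did the interval lie above 0 for both cell lists. The class II median exceeded that of macrophage and dendritic cell genes by 2.83 (interval 0.665 to 3.74) in distal FIP1 and 5.05 (0.998 to 7.20) in proximal FIP2 knockout. In distal FIP2 knockout the excess was 3.22 (-1.18 to 4.94) and in proximal FIP1 knockout 4.94 (-0.538 to 6.33). Over B and plasma cell genes it was 1.80 (-0.359 to 2.68) and 3.19 (-2.72 to 4.97) in distal and proximal FIP1, and 4.26 (-0.349 to 5.42) and 1.46 (-2.79 to 3.68) in distal and proximal FIP2 knockout. Collection of wild-type mice at another time or their being kept apart cannot be told apart from genotype, because wild type is confounded with any such difference; clock genes were called in 4 of 4 comparisons with wild type by camera with its preset correlation. With an estimated correlation the adjusted p was 0.342 and 0.341 for FIP1 and 0.367 and 0.275 for FIP2, distally and proximally, and the proximal FIP1 call was lost without wild-type proximal library 3 (adjusted p 0.0550). Loss of either protein stays open as a biological explanation.

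Wild-type proximal library 2 held more transcripts of forebrain neurons than the other 2 proximal wild-type libraries. The median log2 ratio to them was 1.94 over 34 genes, 25 of them over 2-fold. More enteric neurons in that dissection were argued against as the whole source, since the enteric list had a median of 0.117 over 19 genes. Its members ran from -2.47 to 2.74, with 5 over 2-fold, and those of the forebrain list from -0.796 to 3.16. Forebrain RNA from another library is a possible source of the excess in library 2, with a difference between the lists' medians of 1.83. Forebrain transcripts were not confined to that library. Camk2a was at least 5.332 CPM in every proximal wild-type library. It ran from 2.675 to 2.95 CPM in distal wild type and from 2.47 to 2.565 CPM in distal FIP1 knockout. It was 0.2148 to 0.9357 CPM in proximal FIP1 knockout and 0.3617 to 2.589 CPM in FIP2 knockout. Grin2b ran from 1.672 to 1.906 CPM in distal wild type and from 0.7094 to 1.173 CPM in distal FIP1 knockout. It was at most 0.08716 CPM in proximal FIP1 knockout and at most 0.2584 CPM in FIP2 knockout. The source of the levels outside library 2 was not tested, and no biological explanation was tested.

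Some genes were silent in 1 genotype and expressed in another, 19 in all. Inherited DNA differences between the mouse lines may contribute to the 3 of them that lay within 5 Mb on chromosome 4. Draws gave a 95th percentile of 2 and as many in a share of 0.0380. Reads shared within paralog clusters were not excluded for these. Of the 3 within 5 Mb, Zfp990 and Zfp979 were expressed only in FIP1 knockout. The other, Gm26880, was expressed in FIP2 knockout and undecided in FIP1 knockout. Of the 19 genes 7 were protein coding, and the draws were not matched for gene type or family. Among those 7, Olfr56 and F830016B08Rik were silent in wild type and expressed in both knockouts. Gm12185, Gm4951 and Ltf were silent in wild type, expressed in 1 knockout and undecided in the other, with means there of 3.38, 4.53 and 9.41 CPM. A difference of expression shared by the knockouts was not tested as a source for these genes. The 19 genes lay on chromosomes 1, 4, 5, 6, 7, 9, 10, 11, 12 and 18 and on mitochondrial DNA, while the targets lie on chromosomes 8 and 19. That argues against DNA flanking the targeted alleles for these 19 genes. The share of called genes within 10 Mb of the target reached at most the 79.6 percentile over the 4 comparisons with wild type. This share counts all called genes, so it cannot exclude a few changed genes in the flanks.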

How the results depend on the processing

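No called gene or list that is named changed direction under the alternatives run. Whether more genes were higher or lower did turn in 7 of the 11 comparisons under at least 1 alternative, of which these are examples. Limma on log2(FPKM + 1) gave 1279 higher and 533 lower for FIP1 proximal (edgeR 1185 and 1219), 1503 and 942 for FIP2 distal (1615 and 1659), and 951 and 1313 between segments in wild type (1585 and 1308) and 621 and 662 in FIP2 knockout (882 and 794). DESeq2 turned it for the knockouts compared proximally, with 535 and 499 (edgeR 235 and 251). The deposited FPKM values are scaled to the library total without a TMM factor, so the limma counts differ from edgeR's in scaling as well. TMM factors were 0.814 to 0.949 in proximal wild-type and 0.905 to 1.11 in proximal FIP1 knockout libraries. Leaving them out raises the knockout values relative to wild type there. How much of each turn this accounts for was not tested. Removal of wild-type proximal library 2, of FIP2 knockout distal library 1 and of mitochondrially encoded genes were added after the data were seen. Where a count moved by more than 1.5 times the cause was not tested. In a fit to the compared libraries alone the count of changed genes was 1287 for FIP1 proximal, 1511 for FIP2 proximal and 1810 between segments in wild type. Without a filter it was 1154 for the knockouts compared distally, 1398 proximally, and 644 and 483 for the FIP1 and FIP2 differences between segments. At 10 CPM in 3 libraries it was 140 for the knockouts distally, 1025 between segments in FIP2 knockout and 57 for the FIP1 difference. DESeq2 gave 644 and 1034 for the knockouts distally and proximally, and 326 and 253 for the FIP1 and FIP2 differences. Limma on log2(FPKM + 0.1) gave 204, 261, 53 and 37 in the same order, limma on log2(FPKM + 1) 312 for the knockouts proximally, and without a filter 299 there and 2063 for FIP2 distal. Removing wild-type proximal library 2 gave 512 and 933 for the knockouts distally and proximally. The replicate block gave 262 and 202 for the FIP1 and FIP2 differences, sharing 107 and 56 genes with the 114 and 58, and it ended 15 and added 31 calls of named genes.

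With an estimated correlation the lists called were 3, 5, 0 and 2 for FIP1 distal, FIP1 proximal, FIP2 distal and FIP2 proximal, 0 and 1 for the knockouts distally and proximally, 2, 1 and 3 between segments in wild type, FIP1 and FIP2 knockout, and 1 and 0 for the differences. Beside the counts of 0, camera with the preset correlation called 17, 14 and 19 lists, 5767, 2560 and 1778 genes had an unadjusted p under 0.05, and fry called 19, 4 and 2 lists. Fry gave 4 and 3 for the knockouts distally and proximally, 8 between segments in FIP2 knockout, and 1 and 2 for the differences.

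Leaving out 1 library gave 1775 to 2389 changed genes for FIP1 distal, 1483 to 2374 for FIP1 proximal, 1853 to 2918 for FIP2 distal and 1555 to 3645 for FIP2 proximal. It gave 107 to 256 and 193 to 521 for the knockouts distally and proximally, 695 to 1130 and 1069 to 1385 between segments in FIP1 and FIP2 knockout, and 40 to 153 and 33 to 75 for the differences. Genes shared by the knockouts distally ran from 1068 to 1575, and lists called from 8 to 20 for the knockouts proximally, 9 to 16 between segments in FIP2 knockout and 9 to 18 for the FIP1 difference. Of the named genes' calls, DESeq2 left 890 on the same side of the threshold, ended 5 and added 71; leaving out 1 library left 6140, ended 555 and added 49.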

Other observations

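The genes here were chosen after their values were seen, and the values are given without explanation. The mast cell protease Mcpt1 averaged 9.88 ± 1.30 CPM (SD, n = 3) in distal FIP1 knockout and 6.09 ± 1.83 CPM in distal FIP2 knockout libraries, against 0.753 ± 0.582 CPM in wild type. The fucosyl transferase Fut2 rose by 1.77 ± 0.19 (SE) in distal FIP1 knockout and 1.01 ± 0.18 in distal FIP2 knockout. The class II transactivator Ciita averaged 44.7 ± 20.2 CPM and 50.5 ± 9.63 CPM in the same groups, against 2.43 ± 1.47 CPM. The pentraxin Mptx1 averaged 6454 ± 1541 CPM in distal wild type, 565 ± 241 CPM in distal FIP1 knockout and 2221 ± 1099 CPM in distal FIP2 knockout.

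Single libraries and genotypes also stood apart. Saa1 was 602 CPM in FIP1 knockout distal library 2 and 2.78 and 15.7 CPM in the other two, and proximally 139.5 CPM in library 2 against 0.468 and 2.57 CPM. Ceacam2, which has a close paralog, was 1311 and 1034 CPM in FIP2 knockout distal libraries 1 and 2 and 68.5 CPM in library 3. The mitochondrial transfer RNA genes mt-Tg and mt-Tr averaged 0.0391 and 0.189 CPM in FIP2 knockout, against 13.5 and 5.04 CPM in wild type and 8.90 and 3.38 CPM in FIP1 knockout, and mt-Nd3 lies between them. The pancreatic genes Pnlip, Ctrb1 and Cela2a stood at 28.1, 36.4 and 24.3 CPM in FIP2 knockout distal library 1 and at 3.46, 9.40 and 2.31 CPM in FIP1 knockout distal library 2.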
